A study of Mus musculus with 4 samples.

How the data were processed

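RNA was measured in 4 libraries of mouse bone marrow derived macrophages on the C57BL/6 background, 2 from wild-type control mice (WT) and 2 from mice whose myeloid cells lack Rbpj (RBP-J KO). Per the labels' protocols, marrow was taken from mice of 8 weeks and grown for 3 days with supernatant that contains M-CSF, the growth factor of macrophages, and libraries were made with the Illumina TruSeq RNA protocol. Groups and replicate numbers were taken from the sample titles. No label states that equal numbers mark a shared mouse, litter or day, or that replicates came from separate mice. The values of Ddx3y and Xist given below show that the 2 libraries of each group came from different mice. The p-values measure only the spread between these libraries, which may be partly technical.

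The authors deposited 1 table per library. Per the submitters' processing notes, reads were aligned with TopHat and quantified with Cufflinks against the mouse build mm9; versions, annotation and scaling options are not given in the sources used here. The values deposited by the authors were read as FPKM (fragments scaled by transcript length and library size), the unit that Cufflinks writes, although the file headers name no unit. Their scale is unclear. In the replicate 2 libraries, FPKM times transcript length in kb, with lengths from the GENCODE M21 transcripts for 97.0% of the entries, summed to 5.61 times in WT and 5.32 times in RBP-J KO what the unit's definition gives. Folds between libraries were therefore used and absolute levels only described. Low values showed no whole-read steps, so the sequencing depth is unknown and no counting interval was computed. Genome positions were not analysed here, because the supplied annotation is of another build.

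The 4 tables do not share a layout. Both replicate 1 tables list 22026 genes, and both replicate 2 tables list 27583 transcripts of those 22026 genes; 3573 symbols have several transcripts there. Transcript values were summed per symbol. Among genes above 20 FPKM in every library, the median log2 ratio of WT replicate 1 to summed WT replicate 2 was 0.12 for the 6420 symbols with 1 transcript and 0.14 for the 1114 with 2, so that summing gave like quantities. In the transcript layout, 25 symbols had been turned into calendar dates; they were restored by matching to the other layout, where all 25 had the same description.

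Analysis used R 4.3.3 with limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Values were tested as log2(FPKM + 1), a scale that understates the change of low genes, for the 11851 genes with a mean of at least 1 FPKM over the 4 libraries. A limma model with group as its only term, a variance trend and Benjamini-Hochberg adjustment was fitted (two-sided, threshold 0.05). Fold changes and standard errors (SE) are from this model. Because the replicate numbers divide the libraries technically, the KO to WT difference was also taken inside each pair of equal number (pair 1 and pair 2), and genes with at least a 1.5-fold difference in both pairs were counted by sign. No count model was used, since the files hold no counts.

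A total of 30 gene lists with 645 genes (630 with an entry, 530 measured) was fixed before the data were examined, covering Notch signalling, osteoclast genes, signalling pathways, macrophage and monocyte states, metabolism, proliferation, neighbours of Rbpj and Lyz2, and markers of other marrow cell types. Rbpj was left out of every list. The 28 lists with at least 5 measured members were tested with limma camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the 28 lists), with camera under an estimated correlation and fry beside it. fry tests whether the genes of a list move, on balance, 1 way, without comparing them with other genes. Genes named singly follow a rule fixed at the same time: Rbpj; 10 genes per direction, ranked by the smaller of the 2 within-pair differences among genes with an unadjusted p under 0.05 and 1 sign in both pairs, used because none passed the adjusted threshold; and up to 4 members per list with the smallest p. Predicted models, ribosomal protein genes and genes whose transcripts have different values were left out of the 10. Names outside the rule are said to be chosen after their values were seen.

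The procedure was tested on simulated data built on the 11851 genes, in 10 runs of 200 changed genes each. The changed genes were drawn from those above a minimum mean level. The spread of each gene was drawn around that of its expression class, with the variation between genes estimated from the real data. The model without a block called 0% of genes changed by 1 on the log2 scale, 7% of those changed by 2, 54.8% of those changed by 3 and 82.2% of those changed by 4. With the replicate number as a block the shares were 9.6%, 82.2%, 97.2% and 99.4%, and 0.12% of unchanged genes were called. In the real data the block called 0 genes, although Rbpj, Bend6 and Uchl1 had log2 differences of -2.82, 3.79 and -4.48. The simulated shares can therefore not be read as the power of the block in these data. Within-pair agreement at 1.5-fold recovered 81.8% of genes changed by 1 on the log2 scale and 98.8% of those changed by 2, and also took in 2.03% of unchanged genes. In runs with no change, a median of 241.5 genes went the same way in both pairs and 235.5 opposite ways. The real pairs held 89 genes of opposite signs, so the simulated spread was wider than the real one by this measure. The first version described below gave a median of 62 such genes. Of the lists, 10 of 10 shifted by 0.7 were called, against 0 of 280 unshifted. A first version gave every gene of an expression class the same spread and called 29.4% of genes changed by 2 and 79.2% of those changed by 3; it was replaced after its output was seen, because the genes' variances differ widely in the real data. Simulated genes carry independent noise, so the lists' error rate with co-regulated genes is not covered.

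Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5 FPKM, quantile and upper-quartile scaling, a replicate block, no variance trend, the highest transcript in place of the sum, each library left out, a 2-fold minimum, crossed pairs, and camera with an estimated correlation or on ranks. Alternatives added after seeing the data were genes with 1 transcript entry, and genes above 0 in every library for the within-pair count.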

Results

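RNA levels were compared between macrophages grown from the marrow of wild-type mice and of mice lacking Rbpj in myeloid cells, with 2 libraries per group. Rbpj encodes RBP-J, the DNA-binding protein through which Notch receptors regulate transcription, and the comparison asks which mRNA levels depend on it in these cells. Genes above 0 numbered 12707 in WT replicate 1, 12522 in RBP-J KO replicate 1, 12165 in WT replicate 2 and 12142 in RBP-J KO replicate 2. Summed FPKM per library lay between 2125327 and 2389348, and the 10 highest genes held at most 10.1% of it. Read depth is unknown.

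The replicate number separated the libraries in more than 1 respect. Both replicate 1 tables hold genes and both replicate 2 tables hold transcripts. Ddx3y, a Y-linked gene, was at 193 and 174 FPKM in the replicate 1 libraries and listed at 0 in both replicate 2 libraries, whereas Xist, expressed from the inactive X chromosome, was listed at 0 in replicate 1 and at 268 and 290 FPKM in replicate 2. S100a8, an abundant neutrophil transcript chosen, like Ddx3y and Xist, after the values were seen, was at 2473 and 2971 FPKM in WT and RBP-J KO replicate 1, and at 69.6 and 270 FPKM in replicate 2. By Ddx3y and Xist, the 2 libraries of each group came from mice of different sex. Because of these differences between the replicate numbers, values are given inside each pair of equal number as well as over all libraries.

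Rbpj itself was lower in both RBP-J KO libraries. It stood at 464 ± 154 FPKM (SD, n = 2) in WT and 64.2 ± 18.1 FPKM (SD, n = 2) in RBP-J KO, with 355 against 51.5 FPKM in pair 1 and 573 against 77 FPKM in pair 2. This is a 7.06-fold difference (log2 difference -2.82, SE 0.34), and limma with Benjamini-Hochberg adjustment over all genes gave an adjusted p of 0.457. A gene-level value does not show which exons the remaining RNA contains.

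Differences of several fold were found in both directions. Among genes higher in both RBP-J KO libraries, Hes1, the classical Notch target and a transcriptional repressor, was listed at 0 in both WT libraries and at 30.4 and 8.91 FPKM in RBP-J KO. Cd244, a receptor of the SLAM family, was at 2.67 and 2.54 FPKM in WT and at 51.7 and 102 FPKM in RBP-J KO. Spic, the transcription factor of iron-recycling red pulp macrophages, averaged 9.90 ± 4.75 FPKM in WT and 82.8 ± 28.7 FPKM in RBP-J KO (SD, n = 2), and Ccnd2, a D-type cyclin, 9.73 ± 2.58 and 141 ± 98.9 FPKM. Bend6, a BEN domain protein, was 13.8-fold higher (3.16 ± 0.25 and 56.4 ± 5.23 FPKM; SD, n = 2), and Emr4, an adhesion receptor of macrophages, 11.1-fold higher. The remaining genes named by rule on this side were Gbp8, Gpr18, Ugt1a10 and Pilrb1.

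Uchl1, a ubiquitin hydrolase best known from neurons, had the largest difference among the 10 lower genes named by rule, with 71.7 ± 0.76 FPKM in WT and 2.29 ± 0.54 FPKM in RBP-J KO (SD, n = 2), or 22.3-fold lower. Rgs18, a regulator of G protein signalling, was at 227 ± 33.9 and 34.4 ± 14.1 FPKM. Cacna1a, a calcium channel subunit, was at 48.6 ± 7.23 and 8.17 ± 2.07 FPKM, and Penk, the enkephalin precursor, was at 17.8 and 1.45 FPKM in pair 1 and at 9.45 and 0 FPKM in pair 2. Sncg, Bik and Gchfr were listed at 0 in both RBP-J KO libraries and lay between 4.27 and 8.08 FPKM in WT. Lipn, Grap and Nkain1 completed this side. Spp1, which encodes osteopontin and was chosen after its values were seen, was at 13842 and 9557 FPKM in WT and 1362 and 1112 FPKM in RBP-J KO.

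**Figure D1:**
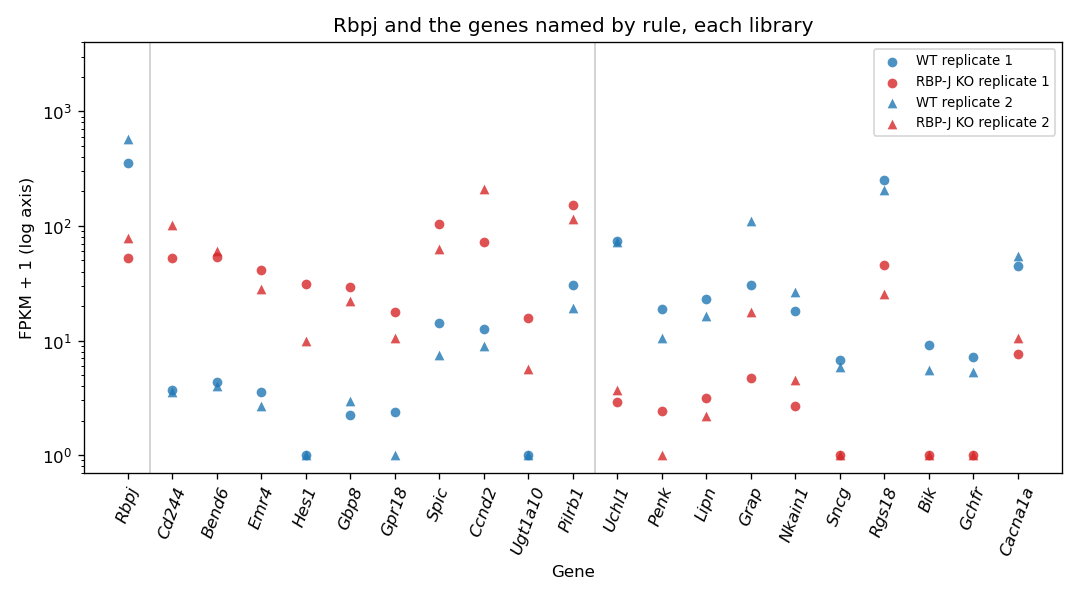
FPKM + 1 on a log axis for Rbpj, the 10 higher genes and the 10 lower genes named by rule, with 1 point per library (blue WT, red RBP-J KO, circles replicate 1, triangles replicate 2). For each gene both RBP-J KO points lie on the same side of the WT point of equal number, as for Uchl1, at 72.3 and 71.2 FPKM in WT and 1.90 and 2.67 FPKM in RBP-J KO.

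None of these genes passed the test. With limma and Benjamini-Hochberg adjustment, 0 of 11851 genes were past an adjusted p of 0.05, the smallest being 0.294 for Bend6 and Uchl1. At an unadjusted p under 0.05 there were 524 genes, 259 higher and 265 lower in RBP-J KO, where chance gives 593. This model leaves the difference between the replicate numbers in its spread, and same-numbered libraries deviated together across genes (r = 0.64). A count below 593 therefore does not show that no gene differed. In limma with the replicate number as a block the count was 1557, again with 0 genes past the adjusted threshold.

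The same-numbered pairs nonetheless differed in the same direction for many genes. A difference of at least 1.5-fold in both pairs was found for 457 higher and 430 lower genes, against 89 genes with opposite signs. Independent pairs with these numbers of changed genes would give 196.5 genes of the same sign and 193 of opposite sign. Across genes, which are not independent replicates, the differences of the 2 pairs had a Pearson r of 0.44 and a Spearman rho of 0.32. With the pairs crossed, 501 genes had the same sign and 1171 opposite signs.

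**Figure D2:**
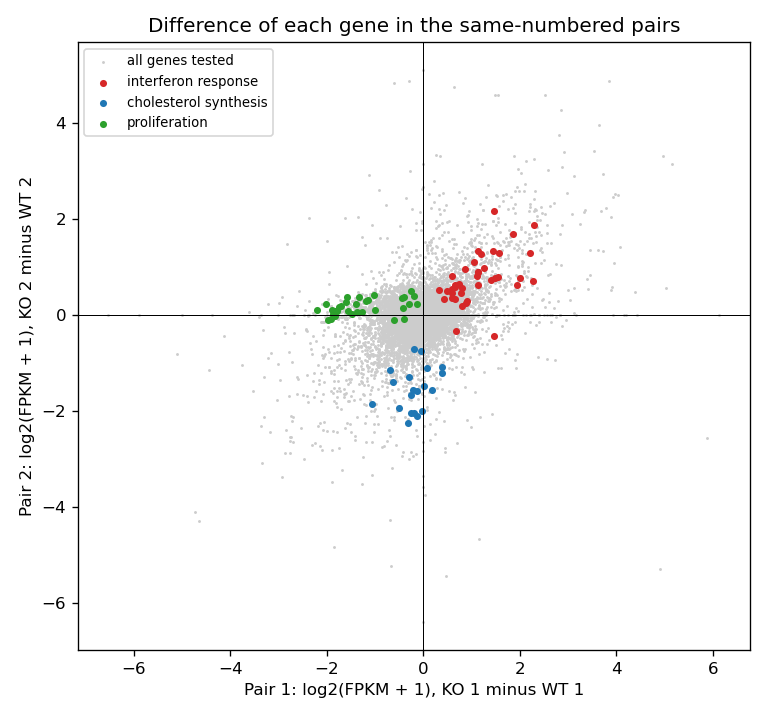
Difference of log2(FPKM + 1) between RBP-J KO and WT in pair 1 (horizontal) and pair 2 (vertical) for the 11851 genes tested (grey), with members of 3 gene lists in colour. Interferon response genes (red) lie in the upper right, with pair medians of 1.10 and 0.71, while cholesterol synthesis genes (blue, -0.19 and -1.58) and proliferation genes (green, -1.41 and 0.14) spread along 1 axis each.

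Of the 28 gene lists tested, 12 passed camera with Benjamini-Hochberg adjustment, 10 higher and 2 lower in RBP-J KO. With an estimated correlation 0 passed, the smallest adjusted p being 0.719, and the smallest adjusted p of fry was 0.911. With 2 libraries per group, camera with an estimated correlation has little power to pass over 28 lists. It was also not tried on simulated data, so not passing there does not show that a list was unmoved. No list member passed the gene-level test over all genes.

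Genes induced by interferon rose as a group in RBP-J KO. Of 39 measured members, 37 were higher in both pairs and 0 lower in both, with a median log2 difference of 0.90 (1.87-fold; camera adjusted p = 2.3e-17 with Benjamini-Hochberg, adjusted p = 0.719 with an estimated correlation). Gbp5, a guanylate-binding GTPase, was at 9.84 and 6.79 FPKM in WT and 52.1 and 27.3 FPKM in RBP-J KO. Irf1, a transcription factor of this response, averaged 140 ± 5.83 and 300.1 ± 86.1 FPKM (SD, n = 2). Mx1, an antiviral GTPase, was 2.96-fold higher in pair 1 and 2.44-fold higher in pair 2, and Ifi47 2.38-fold and 1.97-fold. Adjusted over the list alone 0 members passed, as over all genes. Neutrophil markers had medians of 0.29 in pair 1 and 1.73 in pair 2 beside this list and that of MHC class II.

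The list of MHC class II and costimulatory genes also rose, with 13 of 15 members higher in both pairs and a median log2 difference of 1.34 (camera adjusted p = 1.1e-07 with Benjamini-Hochberg, adjusted p = 0.719 with an estimated correlation). Adjusted over the list alone 2 members passed, against 0 over all genes: H2-DMa, a peptide-loading chaperone, with 38.9 ± 3.28 and 100.3 ± 6.19 FPKM, and Cd86, a costimulatory ligand, with 21.6 ± 0.40 and 101.0 ± 53.9 FPKM (SD, n = 2). H2-DMb1 was 1.91-fold and 1.42-fold higher in the pairs. Cd74, the invariant chain, chosen after its values were seen, was 4.10-fold and 2.55-fold higher. The dendritic cell list, which shares Itgax with the nonclassical monocyte list, rose as well (14 genes, camera adjusted p = 0.0056 with Benjamini-Hochberg, adjusted p = 0.719 with an estimated correlation), but its median was 1.72 in pair 1 and 0.04 in pair 2, and without RBP-J KO replicate 1 the direction turned (camera adjusted p = 0.877). The call was also lost at a minimum mean of 5 FPKM (camera adjusted p = 0.080). Flt3, a dendritic cell growth factor receptor, was at 0.88 and 12.7 FPKM in pair 1 and at 0 and 1.04 FPKM in pair 2.

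Genes of nonclassical monocytes, the patrolling subset of the blood, rose with a median log2 difference of 0.78 (14 genes, 10 higher and 2 lower in both pairs; camera adjusted p = 4.0e-05 with Benjamini-Hochberg, adjusted p = 0.719 with an estimated correlation). Adjusted over the list alone 3 passed, against 0 over all genes. Treml4 was at 31.7 ± 11.1 and 220 ± 30.6 FPKM, and Clec4a1 at 350 ± 33.1 and 935 ± 265 FPKM (SD, n = 2). Fabp4, a fatty acid binding protein in the same list, was lower, at 126 ± 8.01 and 26.8 ± 7.69 FPKM. Cx3cr1, the fractalkine receptor that marks this subset, chosen after its values were seen, was 2.79-fold higher in pair 1 and 23.7-fold higher in pair 2. The list of Ly6C monocyte genes rose as well (15 genes, 9 higher in both pairs, median 0.74; camera adjusted p = 0.045 with Benjamini-Hochberg, adjusted p = 0.719 with an estimated correlation). This call was lost in 8 of 16 alternatives, among them quantile normalization (camera adjusted p = 0.063), no filter, no trend and ranks, and without RBP-J KO replicate 1 (0.230) or WT replicate 2 (0.778). Its members Ms4a4c and Plac8 were at 59.1 ± 39.9 and 33.5 ± 32.1 FPKM in WT, and at 382 ± 377 and 160 ± 146 FPKM in RBP-J KO (SD, n = 2). Adjusted over the list alone 1 member passed, Gm6377, against 0 over all genes. Beside both monocyte lists, neutrophil markers had medians of 0.29 in pair 1 and 1.73 in pair 2.

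Cholesterol synthesis genes fell as a group over all libraries, but mostly in pair 2. None of 20 members was higher in both pairs and 15 were lower in both, with a median log2 difference of -0.91 (camera adjusted p = 3.6e-05 with Benjamini-Hochberg, adjusted p = 0.719 with an estimated correlation). The median was -0.19 in pair 1 and -1.58 in pair 2, where neutrophil markers had medians of 0.29 and 1.73. Sqle, which epoxidises squalene, was at 186 and 88.4 FPKM in pair 1 and at 507 and 139 FPKM in pair 2. Hsd17b7, a sterol reductase of the pathway, was at 47.3 and 30.3 FPKM in pair 1 and at 84.7 and 31.3 FPKM in pair 2. Without WT replicate 2 the list had a median of 0.06, in the opposite direction, so that its fall rested on the level of that library.

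Proliferation genes fell as a group over all libraries, but in pair 1 alone. The median log2 difference of the 33 members was -0.62 (camera adjusted p = 3.3e-04 with Benjamini-Hochberg, adjusted p = 0.719 with an estimated correlation), with -1.41 in pair 1 and 0.14 in pair 2. Mki67, a marker of cycling cells, was at 318 and 85.9 FPKM in pair 1 and at 184 and 185 FPKM in pair 2. Ccnb1, the mitotic cyclin, was at 136 and 28.5 FPKM in pair 1 and at 105 and 112 FPKM in pair 2. No member differed by 1.5-fold or more in both pairs. The call was lost without WT replicate 1 (camera adjusted p = 0.467), and without RBP-J KO replicate 1 the direction turned (0.866).

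**Figure D3:**
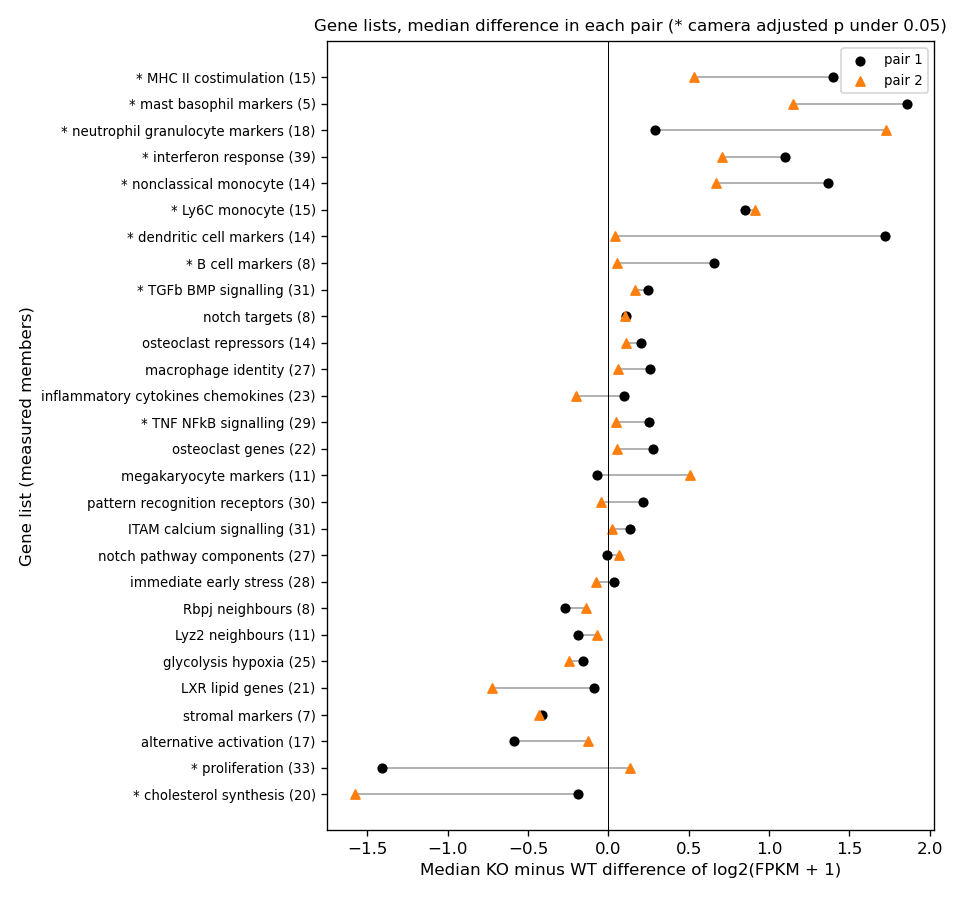
Median difference of log2(FPKM + 1) between RBP-J KO and WT for each of the 28 gene lists in pair 1 (black circles) and pair 2 (orange triangles), with the number of measured members; an asterisk marks the 12 lists past a camera adjusted p of 0.05. MHC class II (1.40 and 0.54) and interferon response genes (1.10 and 0.71) lie to the right in both pairs, and proliferation genes lie at -1.41 and 0.14.

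The list of Notch targets did not pass (8 measured, median log2 difference 0.19, camera adjusted p = 0.127 with Benjamini-Hochberg). Hes1 alone passed adjusted over the list alone (1 gene, against 0 over all genes). Notch1 was at 41.8 ± 0.44 and 52.2 ± 1.03 FPKM (SD, n = 2), and Ccnd1 at 1654 and 800.1 FPKM in pair 1 and at 1039 and 1141 FPKM in pair 2. The Notch pathway components did not pass either (27 genes, median -0.02 with a camera direction upwards, camera adjusted p = 0.401). Maml2 and Maml3, coactivators of the Notch complex, were 1.84-fold and 1.86-fold higher in pair 1 and 1.26-fold and 2.63-fold higher in pair 2. L3mbtl3, a corepressor that binds RBP-J, was at 16.2 ± 7.09 and 29.2 ± 7.47 FPKM (SD, n = 2). Numbl was lower, at 7.97 and 2.98 FPKM in pair 1 and at 6.83 and 5.46 FPKM in pair 2. Of the 27 pathway components, 10 were higher and 11 lower in both pairs.

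The osteoclast list did not pass (22 genes, median 0.11, camera adjusted p = 0.251 with Benjamini-Hochberg), with 10 members higher and 5 lower in both pairs. Without WT replicate 1 (camera adjusted p = 0.013) or RBP-J KO replicate 2 (6.7e-04) the list passed upwards, and without the other libraries its direction turned (0.110 and 0.778). Prdm1, the repressor Blimp1, was at 16.8 and 51.1 FPKM in pair 1 and at 4.25 and 20.3 FPKM in pair 2. Mmp14, a membrane-bound protease, was at 47.7 and 628 FPKM in pair 1 and at 3.18 and 17.8 FPKM in pair 2. Mitf and Atp6v0d2 were lower in both pairs by less than 1.5-fold. Nfatc1, the master regulator of osteoclasts, was at 99.9 ± 7.60 and 115 ± 20.5 FPKM (SD, n = 2), and Ctsk, the collagenase cathepsin K, at 123 and 30.8 FPKM in pair 1 and at 9.43 and 3.86 FPKM in pair 2; both were chosen after their values were seen. The osteoclast repressors did not pass (14 genes, median 0.19, camera adjusted p = 0.0853), but passed without WT replicate 1 (0.0081) or RBP-J KO replicate 2 (0.018). Irf8 was at 321 ± 41.2 and 369 ± 10.3 FPKM (SD, n = 2), while Id1 and Id3, inhibitors of helix-loop-helix factors, were 1.77-fold and 2.33-fold higher in pair 1 and 4.98-fold and 8.74-fold higher in pair 2.

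Signalling through ITAM adaptors and calcium did not pass (31 genes, median 0.02, camera adjusted p = 0.229 with Benjamini-Hochberg). Its members went both ways: Vav2, an exchange factor, was at 35.1 and 85 FPKM in pair 1 and at 33.4 and 80 FPKM in pair 2 and Lcp2, the adaptor SLP-76, at 251 ± 29.3 and 462 ± 80.3 FPKM, whereas Lat2 was at 882 ± 187 and 462 ± 99.95 FPKM and Camkk2 at 127 ± 17.0 and 82.7 ± 3.27 FPKM (SD, n = 2). The TGF-beta and BMP list rose by a small margin (31 genes, median 0.19, 14 higher and 6 lower in both pairs; camera adjusted p = 0.044 with Benjamini-Hochberg, adjusted p = 0.722 with an estimated correlation). Smad3, a transducer of TGF-beta, was at 24.2 ± 4.46 and 49.7 ± 0.66 FPKM (SD, n = 2), and the receptor Tgfbr1 was 2.83-fold and 2.05-fold higher, with Tgfbr2 at 983 ± 6.84 and 786 ± 76.9 FPKM (SD, n = 2). This call was lost under upper-quartile scaling (camera adjusted p = 0.0725), and without RBP-J KO replicate 1 or WT replicate 2 the direction turned (0.877 and 0.948). The TNF and NF-kB list rose with a median of 0.11 (29 genes, camera adjusted p = 0.010 with Benjamini-Hochberg, adjusted p = 0.719 with an estimated correlation), a call that was lost without RBP-J KO replicate 1 (0.731) or WT replicate 2 (0.0617). Its member Nfkbiz was 3.06-fold higher in pair 1 and 1.67-fold in pair 2, and Tnip1 1.75-fold and 1.25-fold.

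Pattern recognition receptors did not pass as a list (30 genes, median 0.09, camera adjusted p = 0.076 with Benjamini-Hochberg), but adjusted over the list alone 4 members passed, against 0 over all genes, and they differed in direction. Without RBP-J KO replicate 2 the list passed upwards (camera adjusted p = 0.015). Nod1, a sensor of bacterial cell wall, was at 27.6 ± 5.40 and 111 ± 16.5 FPKM and Clec4n, the receptor Dectin-2, at 531 ± 77.3 and 1251 ± 46.4 FPKM. Cd14, the lipopolysaccharide co-receptor, was at 1642 ± 103 and 782 ± 25.1 FPKM and Clec4d at 2785 ± 42.8 and 1442 ± 154 FPKM (SD, n = 2). Inflammatory cytokines and chemokines did not pass (23 genes, median 0.12 and mean -0.12 with a camera direction downwards, camera adjusted p = 0.722). Ccl9 was at 2268 ± 265 and 567 ± 284 FPKM (SD, n = 2). The monocyte attractants Ccl2 and Ccl7 were at 3384 and 1945 FPKM in WT replicate 1 and at 191 and 55.6 FPKM in RBP-J KO replicate 1, with 845 and 346 FPKM in WT replicate 2 and 622 and 194 FPKM in RBP-J KO replicate 2. Il1b was at 2.83 and 57.1 FPKM in pair 1 and at 0 and 4.48 FPKM in pair 2.

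The macrophage identity list did not pass (27 genes, median 0.17 and mean -0.08, camera adjusted p = 0.401 with Benjamini-Hochberg). Lyz2, whose locus carries the Cre in the usual myeloid deletion and which has the near-identical copy Lyz1, was at 205 ± 19.0 and 105 ± 14.6 FPKM and Gpnmb at 6012 ± 800.2 and 2824 ± 645 FPKM (SD, n = 2), while Fcgr4 was 2.50-fold and 1.55-fold higher in the pairs. The list of Lyz2 neighbours includes Lyz1 and Lyz2 themselves. It (11 genes, median -0.20, camera adjusted p = 0.140) and the list of Rbpj neighbours (8 genes, median -0.20, camera adjusted p = 0.271) did not pass, the former passing without WT replicate 2. Alternative activation (17 genes, median -0.51, camera adjusted p = 0.401) did not pass, with the folate receptor Folr2 3.54-fold lower. LXR and lipid genes (21 genes, median -0.31, camera adjusted p = 0.0953) did not pass. Pltp, Cd36 and Fabp5 were 2.96-fold, 2.44-fold and 2.30-fold lower over all libraries. Their pairs differed, with log2 differences of -0.72, -1.79 and -0.62 in pair 1 and of -2.41, -0.78 and -1.79 in pair 2. In this list 1 member, Fabp4, passed adjusted over the list alone, against 0 over all genes. This list passed downwards without WT replicate 1 (camera adjusted p = 2.4e-04) or RBP-J KO replicate 1 (0.011). Glycolysis and hypoxia genes (25 genes, median -0.21, camera adjusted p = 0.127) did not pass except without WT replicate 1 (0.0045), with Pgam1 and Hif1a 1.69-fold and 1.39-fold lower. Immediate early and stress genes (28 genes, median -0.02 and mean 0.04, camera adjusted p = 0.401) did not pass; Klf4 was 3.39-fold lower and Ddit3 1.61-fold higher.

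Markers of other marrow cells moved with the groups in part. The neutrophil list rose (18 genes, median 0.96, 12 higher in both pairs; camera adjusted p = 0.016 with Benjamini-Hochberg, adjusted p = 0.719 with an estimated correlation), with medians of 0.29 in pair 1 and 1.73 in pair 2, and the call was lost under quantile normalization (camera adjusted p = 0.054) and without RBP-J KO replicate 1 (0.779). Without WT replicate 2 the direction turned (0.326). The azurophil granule genes Mpo and Prtn3 were 2.16-fold and 2.34-fold higher in pair 1 and 3.99-fold and 4.52-fold higher in pair 2, and the abundant S100a8 and S100a9, chosen after their values were seen, were at 2473 and 2435 FPKM in WT and 2971 and 3047 FPKM in RBP-J KO in pair 1, and 3.84-fold and 3.03-fold higher in RBP-J KO in pair 2. Mast cell and basophil markers (5 genes, median 1.21, camera adjusted p = 0.026 with Benjamini-Hochberg) and B cell markers (8 genes, median 0.35, camera adjusted p = 0.049) rose at low levels, with an adjusted p of 0.719 each with an estimated correlation, and lost the call under quantile normalization (0.054 and 0.105). The B cell call was lost in 10 of 15 alternatives. Without RBP-J KO replicate 1 (camera adjusted p = 0.731 and 0.877) or WT replicate 2 (0.473 and 0.807) neither call was kept. Prss34, a basophil protease, was at 1.88 and 12.2 FPKM in pair 1, and Cd79b at 8.42 ± 2.10 and 23.3 ± 3.71 FPKM (SD, n = 2). Stromal (7 genes, median -0.45, camera adjusted p = 0.344) and megakaryocyte markers (11 genes, median 0.11, camera adjusted p = 0.956) did not pass, though the stromal list did without RBP-J KO replicate 1 (0.014). T and NK cell markers and erythroid markers had 4 measured members each and were not tested, with medians of 0.09 and 0.46.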

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

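All tests of explanations in this part were chosen after the result was seen. The 2 pairs moved apart for proliferation genes: their median log2 difference was -1.41 in pair 1 and 0.14 in pair 2. The difference between the pairs was not tested, since each pair holds 1 library per group.

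Proliferation genes were lower in the RBP-J KO library of pair 1 alone, and cholesterol synthesis genes were lower mostly in pair 2. Both libraries of a pair share a table layout, so that summing treated RBP-J KO and WT alike inside each pair. The 26 proliferation genes with 1 transcript entry, whose values needed no summing, had a median of 0.16 in pair 2 with a spread of 0.18. They are most of the 33 measured members, so this median could hardly differ from the list's 0.14 and does not test the layout. Scaling between libraries is argued against: after quantile normalization the pair 1 median was -1.37, and the cholesterol median in pair 2 was -1.50. The sex of the mice or another difference between the replicate numbers, including growth of the cultures, may lie behind the split. A difference shared by both libraries of a pair cancels inside the pair, so such a factor would have to alter the KO to WT difference itself. This stays open because there is 1 pair per replicate number. Without RBP-J KO replicate 1 the proliferation direction turned, and without WT replicate 2 the cholesterol direction turned. Each split therefore rested on 1 library, RBP-J KO replicate 1 for proliferation and WT replicate 2 for cholesterol synthesis. A deviation of that library cannot be told apart from a KO to WT difference that depends on the replicate number.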

How the results depend on the processing

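Genes with 1 transcript entry and genes above 0 in every library were alternatives chosen after seeing the data. Planned count-based tests were not run, because the files hold no counts, and unknown depth leaves the counting error of low genes unknown. No gene passed the adjusted threshold under any of 14 alternatives; counts at an unadjusted p under 0.05 ran from 307 without RBP-J KO replicate 1 to 1557 with the replicate block, against 524. Rbpj lay between -3.17 and -2.48 over the libraries left out, where the lone library was assumed to vary like the other group. Of 1523 alternative values for 111 genes, 1516 kept their direction; of 443 for lists, 361 kept direction and side, 43 lost the threshold, 13 gained it and 26 reversed. The cause of the changes below was not tested.

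Same-numbered libraries deviated together from their group means across genes (r = 0.64), but the labels tie them by number only. The replicate block brought the osteoclast genes (adjusted p = 0.043) and osteoclast repressors (0.0077) past the threshold, reversed cytokines (0.752) and changed no other call.

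The TGF-beta list lost its call without a filter (0.074), with quantile normalization (0.054), upper-quartile scaling (0.072) or no trend (0.060). An estimated correlation left 0 lists past the threshold, with 0.722 for TGF-beta and 0.719 for interferon response, MHC class II, nonclassical monocyte, proliferation and cholesterol genes. Both scalings left 7 of 12 lists. Megakaryocyte markers reversed with a pseudocount of 5 (0.924), a mean of at least 5 FPKM (0.606), quantile normalization (0.726) and upper-quartile scaling (0.736), and cytokines on ranks (0.967). Of 887 genes changed the same way in both pairs, 388 did so at 2-fold; crossed pairs gave 501, and other settings 617 to 1048.

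Over the libraries left out, 6 to 15 lists passed. Adjusted p ran from 6.7e-04 to 0.778 for osteoclast genes, 4.5e-04 to 0.948 for TGF-beta, 1.8e-14 to 0.866 for proliferation, 1.1e-25 to 0.514 for cholesterol, 1.7e-08 to 0.877 for dendritic, 1.0e-08 to 0.779 for neutrophil, 0.0045 to 0.783 for glycolysis, 0.014 to 0.639 for stromal, 0.115 to 0.986 for Rbpj neighbours, 0.130 to 0.844 for Notch pathway, 0.078 to 0.887 for alternative activation, 0.102 to 0.841 for macrophage identity, 0.189 to 0.877 for immediate early, 0.110 to 0.223 for megakaryocyte and 0.102 to 0.986 for cytokine genes, each reversing at least once. Log2 differences ran from -3.32 to 0.25 for Ctsk, -0.48 to 3.62 for Id1, -0.66 to 5.01 for Id3, -1.46 to 3.67 for S100a8 and -1.27 to 3.19 for S100a9.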

Other observations

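The gene groups and all tests of explanations in this part were chosen after the values were seen. Interferon-inducible GTPases were higher in RBP-J KO for 16 of 17 measured members in both pairs, with a median log2 difference of 1.64. Of all genes tested, 25.1% were higher in both pairs. The group is not separate from results above: Gbp2, Gbp3, Gbp5 and Ifi47 are also in the interferon response list, and Gbp8 is among the 10 higher genes named by rule. Iigp1 was 6.19-fold higher in pair 1 and 4.79-fold higher in pair 2, and Tgtp1 was at 13.8 and 71.1 FPKM and at 9.52 and 54.8 FPKM. MHC class I presentation genes were higher in both pairs for 21 of 25 members and lower for 3, with a median of 0.67. H2-Q6 was at 42.2 and 147 FPKM in pair 1 and at 44.2 and 152 FPKM in pair 2, and the transporter Tap1 at 183 and 397 FPKM and at 132 and 258 FPKM. None of these genes passed the limma test over all genes.

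Among 18 selected genes, mostly of S100 proteins, annexins, galectins and actin-binding proteins, 15 were lower in both pairs. The 18 had a median log2 difference of -0.82 and were not tested as a list. Of all genes tested, 34.1% were lower in both pairs. Tmsb4x, S100a1 and Anxa5 went opposite ways in the pairs. This group leaves out S100a8 and S100a9, which stand in the neutrophil list and were higher in both pairs. Tmsb10, which binds actin monomers, was at 373 and 121 FPKM in pair 1 and at 363 and 115 FPKM in pair 2, and S100a4 at 5461 and 1737 FPKM and at 8687 and 2629 FPKM. Iron and heme genes went both ways, 7 higher and 7 lower in both pairs of 16. The iron exporter Slc40a1 was at 895 and 4076 FPKM in pair 1 and at 1374 and 6159 FPKM in pair 2, while the heme oxygenase Hmox1 was at 3224 and 1439 FPKM and at 3234 and 1853 FPKM. Receptors for apoptotic cells also went both ways, 6 higher and 6 lower in both pairs of 12, with Axl 7.01-fold and 13.3-fold higher in the pairs and Cd36 2.44-fold lower over all libraries.

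Interferon response and MHC class II genes were higher in the RBP-J KO library of both pairs. Scaling between libraries is argued against, since the interferon median was 0.94 after quantile normalization and that of MHC class II 1.27. More RNA of mature neutrophils in pair 1 is argued against as well, because their 6 abundant genes, azurophil granule genes left out, had a median of 0.17 there with a spread of 0.18, against 1.10 for the interferon list. RNA of granulocyte precursors in pair 1, where the azurophil granule genes Mpo, Elane, Prtn3 and Ctsg had a median of 1.11, and neutrophil RNA in pair 2, where the list had a median of 1.73, stay open. A response to interferon made by the cultured macrophages may also be at work, but 0 of 17 interferon genes were above 0 in any library, which decides nothing without a known depth.

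No gene passed the adjusted threshold although the pairs went the same way. Spread between the replicate numbers may be part of this and stays open: with the replicate number as a block, 1557 genes had an unadjusted p under 0.05 in limma, against 524 without it, but still 0 passed, the smallest Benjamini-Hochberg adjusted p being 0.064. Groups of co-regulated genes lining up by chance in 2 pairs stay open, since the 89 genes with opposite signs against 887 with the same sign come from 2 pairs of libraries.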
